A study of Mus musculus with 8 samples.

How the data were processed

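Cultured satellite cells of Dnmt3a-KO and WT mice were profiled on 8 one-colour (Cy3) Agilent mouse arrays of 1 design, with 1 array per genotype on each of days 2, 4, 5 and 6 of differentiation. Groups, days and genotypes come from the labels. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 11.0.1.1 on a G2505C scanner for both day 2 arrays and 9.5.3.1 on a G2505B scanner for the other 6, and the processed signal was taken as the intensity of a spot. The submitters' processing notes name Feature Extraction 9.5 alone. The deposited value table of the series holds a score per spot. Set against the scanner signals, this score is the processed signal times 100 over the array's 75th percentile, with negative values set to 0 and rounded to whole numbers, so its scale is known. Its column medians were 6 on each array. No value table column of another sample was present. The day 4 to 6 files hold 4775 to 5797 spots at or below 0, and the day 2 files hold none.

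From the processed intensity, each array was divided by its 75th percentile over 43020 non-control spots, values under a common floor of 0.00763 (the lowest scaled signal well above background on any array, -7.03 on the log2 scale) were set to it, and log2 was taken. Spots flagged as non-uniform or population outliers were left out, spots of 1 probe were averaged, and 273 probes with no usable spot on some array were left out. Of 39429 probes, 26055 matched a RefSeq gene of GRCm38.p6 by accession, which updated 3358 symbols, and the others kept the name in the files. Only 9.1% of matched probe coordinates lie inside their gene on that assembly, so it was used for names and gene order and none of its coordinates are given. One probe per gene was kept, the one with the highest mean, and 19663 genes well above background on at least 4 of 8 arrays were tested. Replicate spots of 255 probes had a median SD of 0.066 to 0.16 log2 units within an array.

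Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype effect is Dnmt3a-KO minus WT with day as a block, which also takes out the slide and leaves 3 residual degrees of freedom. The day slope is log2 signal per day with genotype as a covariate and 5 residual degrees of freedom. The interaction of genotype and day has 2. Differences of single days have no test, and a gene was counted at 2-fold or more with the brighter array well above background. A group in which no array was well above background gives a bound: the fold is taken against the higher of the dim probe's own signal and the lowest signal well above background on each array, and written as at least N-fold. SDs of genotype differences are over the 4 days.

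Before the data were examined, 26 gene lists and the naming rule were fixed. The lists were DNA methylation machinery, satellite cell and quiescence, myogenic regulators and fusion, sarcomere and contraction, BMP and GDF pathway, TGF-beta and activin pathway, cell cycle, imprinted genes, germline genes silenced by DNA methylation, cellular senescence and p53 targets, interferon response, inflammatory cytokines and chemokines, extracellular matrix, fibro-adipogenic and fibroblast markers, adipocyte markers, macrophage and leukocyte markers, endothelial markers, smooth muscle and pericyte markers, Schwann cell and neural markers, tendon, cartilage and bone, oxidative phosphorylation, glycolysis, muscle atrophy and ubiquitin ligases, endoplasmic reticulum stress, Wnt pathway and Y-linked genes. They were tested with camera at a preset correlation of 0.01 and again with an estimated one, and with fry. Named were Dnmt3a and Gdf5, the 12 largest rises and 12 largest falls of the genotype effect with the same direction on 4 days, filled with genes not past the threshold where fewer passed, the 10 largest rises and falls of the day slope past it, the 5 largest of each day and direction, and up to 2 members per list and direction. Names without a gene symbol were counted and skipped.

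The steps were tested on simulated data with the real design and 19663 genes. For the genotype effect, 92.0% of 100 genes changed by 1 log2 unit and 95.0% of 100 changed by 2 were recovered, with 17 false calls. For the day slope, 89.0% of changes of 0.5 per day were recovered, and for the interaction 53.0%. In simulated data without a changed gene the genotype test called 0. The simulated noise was drawn independently for each gene from the variance of its fit, so variation shared by genes of an array was absent. The shares recovered therefore check the steps and do not give the power in the real arrays. Alternatives covered the scaling, the background correction, the filter on dim probes, 1 or all probes per gene, the variance model, array weights, the block, the deposited score, the fold threshold and leaving out each day. The mean spot signal is not in every file, so normexp with an offset of 50 used the median signal.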

Results

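Satellite cells, the stem cells of skeletal muscle, were taken from the extensor digitorum longus, a fast hindlimb muscle, of mice lacking Dnmt3a and of wild-type (WT) littermates. Dnmt3a encodes a de novo DNA methyltransferase. The cultured cells were moved to differentiation medium, in which satellite cell progeny fuse into myotubes, and RNA was profiled on 1-colour Agilent arrays on days 2, 4, 5 and 6. Each genotype had 1 array per day, so 8 arrays were compared, 4 per genotype, and no group of a genotype and day was repeated. The labels do not say whether the days came from separate animals. The sex-linked transcripts given below part day 2 from days 4 to 6, which argues against the same mice on day 2 and on the later days. Days 4 to 6 may still come from the same mice or culture, so the 4 days may not be 4 independent pairs. The p-values below therefore measure the spread of the genotype difference between days, or of the arrays around a trend, which may be partly technical. Between 61.6% and 67.4% of the 43020 non-control spots of an array were well above background, and the 75th percentile of the signal ran from 719.5 to 1528.1 intensity units. Both day 2 arrays were on a slide of their own, scanned in a separate session on another scanner model, and their signals were extracted with another version of the software. The number of arrays limits the precision of every value.

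The first question was whether the arrays carry the genotypes they are labelled with. Dnmt3a signal was lower in the Dnmt3a-KO array on each day, at 46.2% of WT on day 2, 19.8% on day 4, 21.7% on day 5 and 19.1% on day 6. The mean log2 difference was -2.01 ± 0.60 (SD over 4 days), and it did not pass the threshold over all genes (limma adjusted p = 0.10). Gdf5, which encodes a growth factor of the BMP family, was brighter in the Dnmt3a-KO array on each day, with log2 differences of 2.90, 2.57, 1.71 and 2.45 on days 2, 4, 5 and 6. Its mean difference was 2.41 ± 0.50 (SD over 4 days), a 5.3-fold higher signal, with a limma adjusted p of 0.066. A second Gdf5 probe gave 2.42 ± 0.35. The Dnmt3a probe, A_55_P2178084, lies on chromosome 12 at 3914320 to 3914379. The Gdf5 probes lie on chromosome 2, A_66_P127070 at 155766801 to 155766860 and A_55_P2131831 at 155768050 to 155768109. These positions are those in the array files, whose genome build is not given in the sources used here, so the probes were not placed in exons. Whether the Dnmt3a probe lies in the deleted part of the gene is likewise not given, so the signal left in Dnmt3a-KO cells has no reading as residual function.

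**Figure D1:**
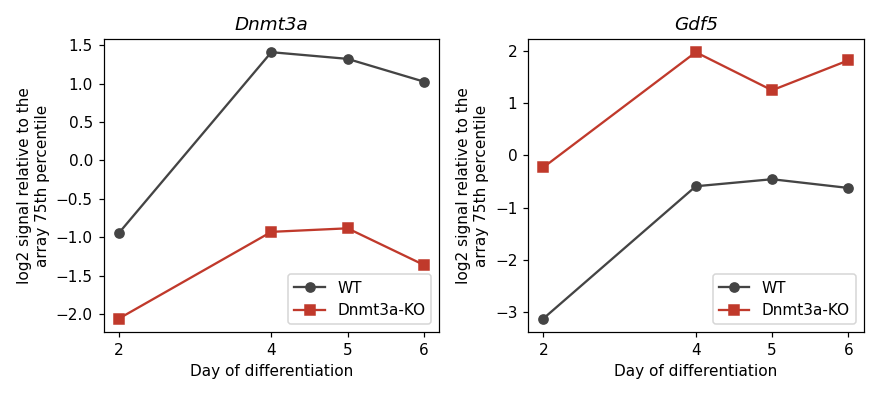
Signal of Dnmt3a (left) and Gdf5 (right) on each array, as log2 relative to the 75th percentile of that array, against the day of differentiation, with 1 array per point. Dnmt3a lies lower and Gdf5 higher in Dnmt3a-KO than in WT on all 4 days.

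The sex-linked transcripts did not follow the labels, which call all mice male. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background on both day 2 arrays and on none of the 6 later arrays. Xist, the RNA that coats the inactive X chromosome, was well above background on all 6 later arrays and on neither day 2 array. Eif2s3y was at least 343-fold and Ddx3y at least 136-fold brighter on day 2, and Xist was at least 74.8-fold brighter on the later days by one probe and at least 36.9-fold by the other. Within a day both genotypes had the same calls above background in these genes. Day 2 thus differed from days 4 to 6 in these transcripts as well as in slide, scan session, scanner and software version, while every day held both genotypes.

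The main comparison asked which transcripts differed between Dnmt3a-KO and WT cells over the 4 days. Myh6, which encodes the alpha cardiac myosin heavy chain, fell by 1.37 ± 0.075 on the log2 scale (SD over 4 days), to a 2.59-fold lower signal, with a lower value on 4 of 4 days (limma adjusted p = 0.042). The next 3 genes were lower on all 4 days without passing the threshold, while the sarcomere list, which holds Myh7 and Myl2, had no call and a median of 0.001. Myh7, the slow myosin heavy chain, differed by -2.06 ± 0.69 (adjusted p = 0.11), Myh7b by -1.63 ± 0.71 and Myl2, a slow regulatory light chain, by -1.65 ± 1.0. On the other side Gdf7, a second BMP family ligand, was 3.82-fold higher at 1.93 ± 0.37 (adjusted p = 0.066), beside Gdf5.

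Of 19663 genes tested with limma, with day as a block, 2 passed an adjusted p of 0.05, Myh6 and the predicted gene Gm3866, which rose by 1.84 ± 0.18 (adjusted p = 0.042) and is named here after its value was seen because the naming rule skips such symbols. At an adjusted p of 0.1 there were 19 higher and 23 lower genes, and 2530 genes had an unadjusted p under 0.05 against 983 expected by chance. None of the other genes in this paragraph passed. The next ranking covers only genes with a symbol that were higher on all 4 days. Its largest mean differences were those of Gdf5, Mmp3, Gdf7, Perp, Tbr1, Svop, Igfbp4, Slc52a3, Lrrc26, Mmp10, Ripk4 and Wnt10b. 0610040J01Rik, skipped by the naming rule and named after its value was seen, averaged 3.44 and was also higher on all 4 days. The stromelysins Mmp3 and Mmp10 degrade extracellular matrix. Mmp3 was not well above background on any WT array and was at least 4.06-fold higher, and Mmp10 was 2.74-fold higher. Perp, a p53 target, differed by 1.76 ± 0.75. Tbr1, a T-box transcription factor of neurons, was also not well above background on any WT array and was at least 2.34-fold higher. Wnt10b, a Wnt ligand, differed by 1.37 ± 0.40, Svop by 1.54 ± 0.61 and the riboflavin transporter Slc52a3 by 1.51 ± 0.39. Igfbp4, a binding protein of insulin-like growth factors, averaged 1.52 ± 1.85, with 4.17 on day 2. Lrrc26 and Ripk4 averaged 1.47 and 1.41 with lowest days of 0.028 and 0.003. Slc52a3 was well above background on 2 of 4 WT arrays and Ripk4 on 1 of 4, so the size of either is uncertain.

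Genes with a symbol that were lower on all 4 days were ranked by mean difference in the same way. The largest were those of Pkp1, Pcp4l1, Myh7, Dnmt3a, Eps8l1, Mest, Tmem39a, Grik3, Pde1a, Myl2 and Myh7b. Names without a symbol were again skipped, including one with a mean of -2.22. Pcp4l1 differed by -2.18 ± 0.62 and was well above background on 1 of 4 Dnmt3a-KO arrays and 4 of 4 WT arrays, as was Eps8l1 at -2.01 ± 0.95, so the size of either is uncertain. The imprinted gene Mest differed by -1.86 ± 1.23, and 2 of its 2 other probes had the same sign. The kainate receptor gene Grik3 differed by -1.83 ± 0.97 and the phosphodiesterase gene Pde1a by -1.74 ± 0.76. Both were well above background on 2 of 4 Dnmt3a-KO arrays, so their sizes are uncertain as well. Pkp1, a desmosomal plakophilin, averaged -2.28 ± 2.15 and was at least 44.4-fold lower on day 5, and Tmem39a averaged -1.85 ± 3.22 and was at least 96.3-fold lower on day 2. On those days neither was well above background in Dnmt3a-KO, so 1 array decides the mean of each. Leaving out any 1 day left 0 genes past the limma threshold, with 1449 to 2538 genes at an unadjusted p under 0.05, while day as a random block gave 128 genes. The call of Myh6 was lost with quantile scaling (adjusted p = 0.062) and without any 1 day (adjusted p = 0.12 to 0.31).

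**Figure D2:**
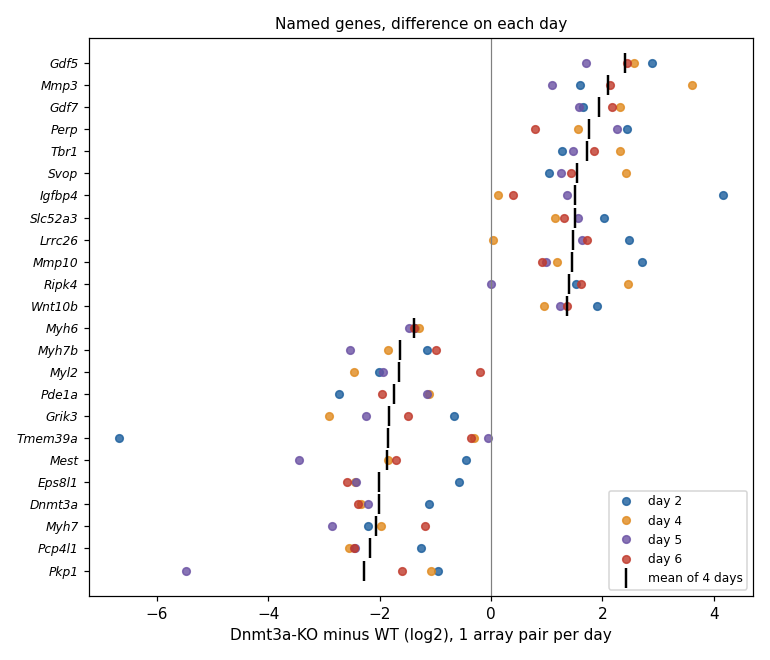
Log2 difference between the Dnmt3a-KO and the WT array of each day for the 24 genes named by the fixed rule; points are single days and black ticks the mean of 4 days. Myh6 has the narrowest spread, from -1.47 to -1.29, while Tmem39a and Pkp1 each have 1 day far from the others.

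Gene lists were fixed before the data were examined, and shifts were tested with camera at a preset correlation of 0.01, with adjustment over 25 lists. Cell cycle transcripts were lower in Dnmt3a-KO cells on days 2, 4 and 6, with list medians of -0.90, -1.05 and -0.81, and not on day 5, with a median of 0.011. None of the 44 measured members passed over all genes, and 33 fell adjusted over the list alone. The mitotic kinase gene Cdk1 differed by -1.09 ± 0.56 and the phosphatase gene Cdc25c, well above background on 1 of 4 Dnmt3a-KO arrays and so of uncertain size, by -1.3 ± 0.83, whereas Rrm2 averaged 0.13 and E2f8 0.071. The list shifted down by camera (adjusted p = 4.4e-16), a call lost with an estimated correlation (adjusted p = 0.53). Markers of fibro-adipogenic cells and fibroblasts had medians of 0.66, -0.84, -0.077 and -0.43 on days 2, 4, 5 and 6, so they ran with the cell cycle list on days 4 and 6 and against it on day 2. Without day 2, 4 or 6 the members of the cell cycle list that fell adjusted over the list alone numbered 1 to 2, and without day 5 there were 38.

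Energy metabolism transcripts had lower medians in Dnmt3a-KO cells on days 4 and 5 and medians near 0 on days 2 and 6. On days 2, 4, 5 and 6 these were -0.035, -0.25, -0.21 and 0.012 for oxidative phosphorylation and 0.031, -0.35, -0.22 and -0.060 for glycolysis. Over the 4 days the oxidative phosphorylation list had a median of -0.14, with 0 of 37 members past the threshold over all genes or adjusted over the list alone (camera adjusted p = 7.4e-05, and adjusted p = 0.74 with an estimated correlation). Cox6a2, the muscle form of a cytochrome c oxidase subunit, differed by -0.67 and Atp5c1 by -0.30, while Cox8b averaged 0.17. The glycolysis list had the same median of -0.14, with 0 of 23 members past either threshold (camera adjusted p = 0.0020, and adjusted p = 0.74 with an estimated correlation). Its members Pfkp and Hk2, encoding a phosphofructokinase and a hexokinase, differed by -0.43 and -0.42, and Aldoc by 0.15. The fibroblast and extracellular matrix medians of day 4 were also below 0. The sarcomere list was lower on the same 2 days, with medians of 0.21, -0.19, -0.16 and 0.066 on days 2, 4, 5 and 6. Myogenic regulators had medians of 0.13 on day 4 and -0.12 on day 5. Days 4 and 5 shared a slide that held both genotypes, so a shift of the whole slide cancels in these differences. A genotype difference particular to that slide cannot be told apart from one of these days.

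Satellite cell and quiescence transcripts were lower as a list, at a median of -0.12. Of 22 measured members 0 passed over all genes, and 4 fell and 1 rose adjusted over the list alone. Fgfr4, a growth factor receptor of myoblasts, fell by 1.33 ± 0.37 and Heyl, a Notch target, fell by 1.04 ± 0.45 by that adjustment, and Megf10 rose by 0.39 ± 0.18. Rgs5 averaged 0.40 ± 1.42. The camera call (adjusted p = 0.015) was lost with an estimated correlation (adjusted p = 0.53), and fry, which asks whether a list moves one way on balance, gave an adjusted p of 0.020. The list of the DNA methylation machinery had a median of -0.098 and a camera adjusted p of 0.038. That call was lost with an estimated correlation (adjusted p = 0.53), and fry gave this list an adjusted p of 0.020 as well. Adjusted over the list alone, 2 of its 16 members fell, Dnmt3a itself and Uhrf1 at -0.69 ± 0.36, and its largest positive values were 0.47 for Mbd4 and 0.22 for Uhrf2. That list holds the deleted gene, so its direction is not independent of the design.

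BMP and GDF pathway transcripts shifted up at a median of 0.11 (camera adjusted p = 0.015). With an estimated correlation (adjusted p = 0.53) and by fry (adjusted p = 0.090) there was no call. The list medians were 0.24, 0.011, 0.062 and 0.071 on days 2, 4, 5 and 6, so day 2 had the largest shift. Of 25 measured members 0 passed over all genes and 4 rose adjusted over the list alone, led by Gdf5 and Gdf7. The list mean of 0.28 lay above its median. Gdf5 was also set for naming in advance, so the choice of this list may not be independent of it. The receptor gene Bmpr1b differed by -0.49 ± 0.42 and Gdf15 by -0.20. Genes of cellular senescence and p53 targets shifted up at a median of 0.13 (camera adjusted p = 0.0053, and adjusted p = 0.53 with an estimated correlation), with 5 of 23 members up and 1 down adjusted over the list alone. The death receptor gene Fas rose by 1.02 ± 0.42 and Perp rose by 1.76 ± 0.75 by that adjustment, while Lmnb1 differed by -0.58. The list of muscle atrophy and ubiquitin ligases shifted up at a median of 0.036 (camera adjusted p = 0.038, and adjusted p = 0.53 with an estimated correlation). Adjusted over the list alone 1 of its 20 members rose, Gadd45a, a growth arrest gene, by 0.74 ± 0.15. Its ubiquitin ligase Fbxo32 differed by 0.44, Foxo4 by -0.20 and Fbxo21 by -0.10.

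Markers of other cell types showed no list call except that of Schwann cells and nerve, whose median was -0.19 with 0 of 13 members past either threshold (camera adjusted p = 0.038, and adjusted p = 0.53 with an estimated correlation). Its members Nefl and S100b differed by -0.70 and -0.53. The fibro-adipogenic list had a camera adjusted p of 0.19, with Dcn at 0.74, Pdgfra at 0.48, Pi16 at -1.06 and Col3a1 at -0.92. Adipocyte markers gave 0.090, with Cd36 at -0.43, Slc2a4 at -0.37 and Lpl at 0.056, and macrophage and leukocyte markers gave 0.077, with S100a8 at -0.57, Fcer1g at -0.32 and Mrc1 at 0.13. Endothelial markers gave 0.87 and their median of 0.071 opposed their mean of -0.14, with Flt1 at -1.52 and Robo4 at 0.30. Smooth muscle and pericyte markers gave 0.82, with Cnn1 at -0.81 ± 2.41, Notch3 at -0.66 and Cspg4 at 0.29.

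The remaining lists gave no call for the genotype. The extracellular matrix list had an adjusted p of 0.22 with medians of 0.19, -0.62, 0.21 and -0.63 on days 2, 4, 5 and 6, and Postn averaged -1.55 ± 2.07 in it. The sarcomere list gave 0.78. Its median of 0.001 and its mean of -0.093 differed in sign, and adjusted over the list alone 1 of 49 members fell, Myh7, while Pvalb averaged 0.79 and Mybpc2 0.53. Myogenic regulators gave 0.36, with Myf6 at 0.61 and the cell cycle inhibitor Cdkn1c at -0.92. The TGF-beta list gave 0.13 with a median of 0.071 against a mean of -0.011, with Inhba at 0.47 and Acvr2b at 0.40. Imprinted genes gave 0.79, and adjusted over the list alone Peg10 fell by 1.06 ± 0.18 and Plagl1, a zinc finger gene, rose by 0.60 ± 0.28, while Dlk1 averaged 0.99 ± 0.62. The Wnt list gave 0.72, up by camera and down by fry, and adjusted over the list alone 1 of 21 members fell, the receptor gene Fzd4, by 0.86 ± 0.12, while Wnt10a averaged 0.98. Of 34 germline genes silenced by DNA methylation 7 were measured, with an adjusted p of 0.26 and Rhox5 at -0.97. Interferon response genes gave 0.37, with Cxcl10 at 0.78, and inflammatory cytokines 0.52, with Il33 at 1.14, Lif at 1.13 and Il6 at -1.07. Endoplasmic reticulum stress gave 0.36, with Dnajb9 at 0.26 and Atf3 at -0.39. Tendon, cartilage and bone gave 0.71, with a median of 0 and a mean of 0.083, and Sp7 at 0.89. The 4 Y-linked genes were above background on too few arrays to enter the fit.

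**Figure D3:**
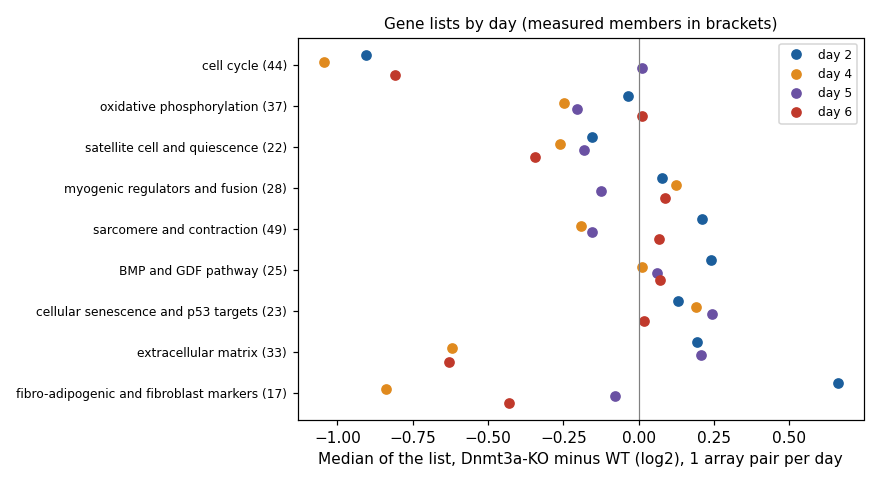
Median log2 difference between Dnmt3a-KO and WT over the measured members of 9 gene lists, 1 point per day and 1 pair of arrays per point. Cell cycle medians lie at -0.90, -1.05 and -0.81 on days 2, 4 and 6 and at 0.011 on day 5, and fibroblast markers lie at 0.66 on day 2 and -0.84 on day 4.

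The next comparison described each day on its own, with 1 array per genotype and hence no test. On day 2, 573 genes were at least 2-fold higher and 445 at least 2-fold lower in Dnmt3a-KO cells. On day 4 the numbers were 482 and 778, on day 5 they were 334 and 616, and on day 6 they were 499 and 554. These counts depend on the processing, as day 5 had 480 higher and 516 lower with quantile scaling, and normexp left 64, 131, 68 and 80 genes on days 2, 4, 5 and 6. On all 4 days, 11 genes were at least 2-fold higher and 14 at least 2-fold lower. If days were independent and every gene had the same chance, 0.00038 and 0.0014 would arise. Genes that vary more on every day, such as dim ones, break the second condition, so these expectations are too low. With quantile scaling the numbers were 13 higher and 10 lower, and with normexp 1 and 2. With both arrays of each day well above background they were 7 and 10. The higher genes with a symbol were Gdf5, Mmp3, Gdf7, Tbr1, Svop, Slc52a3 and Mss51, and the lower ones Dnmt3a, Pcp4l1, Myh7, Myh6, Tac2, Usf3, Ckap2l, Capn6, Ccdc80 and Gtpbp8, of which those outside the naming rule are named after their values were seen. Across genes, which are not independent replicates, the differences of 2 days correlated at a Pearson r of 0.13 to 0.21, except days 4 and 6 at 0.50.

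Among genes with a symbol, the largest values of single days mostly belonged to transcripts near background on one array. On day 2 the leading higher genes were Igfbp4, 18-fold, Skint6, Ms4a5, Agtr2 and Olfr1445, the last 4 at least 11.2-, 10.6-, 9.36- and 8.78-fold. The leading lower genes that day were Med4, Tmem39a, Ceacam11, Cdkl4 and Olfr360, with Med4 152-fold lower and 0.040 to 0.23 on the log2 scale on the other days. On day 4 Miox, Polr2b, Mmp3, Pebp4 and Gdpd2 led the higher genes, and Rbm8a, Galnt3, Pcdh20, Postn and Vmn1r50 the lower, with Rbm8a at least 714-fold lower and within 0.10 on the other days. The matricellular protein gene Postn was 21.8-fold lower on day 4. On day 5 Tac1, Pygo1, Myo1g, Vmn1r219 and Vmn1r71 led the higher genes with a symbol, at least 9.99-fold, and Gpr3, Pkp1, Uox, Rbbp9 and Klk7 the lower, at least 17.3-fold. On day 6 Calcoco2, Klra5, Agxt2, Foxn4 and Dct led the higher genes, and Rbbp9, Arid3c, Olfr530, Il22ra2 and Uts2 the lower. Rbbp9 was at least 20.5-fold lower on day 5 and at least 28.2-fold lower on day 6, against log2 differences of 0.53 and -0.078 on days 2 and 4.

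The time course asked which transcripts followed the day of differentiation in both genotypes. Myh2, the fast IIa myosin heavy chain, rose by 2.28 ± 0.46 per day on the log2 scale (slope and SE), and its mean over days 4 to 6 was 456-fold above day 2 (limma adjusted p = 0.014). Atp1b4, a muscle protein of the inner nuclear membrane, rose with a level at least 193-fold above day 2, Smtnl1 131-fold, and the collagen cross-linking enzyme gene Lox 77.1-fold. The proenkephalin gene Penk rose 51.3-fold, Igsf1 92.4-fold and Dupd1 89.7-fold, and Thrsp, Lce1f and Xist rose at least 90.9-, 89.3- and 74.8-fold. Among tested genes the largest falls were those of Cpa1, 53.9-fold, Syt10, 56.0-fold, Mest, 32.3-fold, and Eya2, a transcriptional cofactor in myogenesis, 23.1-fold. Transcripts well above background on the day 2 arrays alone were not tested, such as Eif2s3y and Ddx3y, at least 343-fold and 136-fold lower on the later days. Rgs5, Gbp9, Duxbl1, Sema6b, Ripor2 and Pabpn1l fell 18.3-, 16.3-, 15.4-, 15.2-, 13.7- and 13-fold. Many of these slopes were a step after day 2, since over days 4 to 6 they were 0.029 for Myh2, -0.058 for Atp1b4, -0.089 for Smtnl1, -0.002 for Dupd1, 0.064 for Syt10 and 0.24 for Mest, against 0.97 for Penk and -0.66 for Ripor2.

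In all, 8921 genes had a slope past the threshold, 5097 up and 3824 down, against 4203 and 4025 with quantile scaling and 3562 and 4086 with normexp. The filter on dim probes kept transcripts seen only on the later arrays and dropped those seen only on day 2. Rises and falls were therefore not filtered alike. With probes well above background on at least 1 array, 5261 rose and 4134 fell. This comparison rests on day 2, which also differed in sex-linked transcripts, slide and scan session. Without day 2, limma called 0 slopes, with 1574 at an unadjusted p under 0.05, and the difference of days 5 and 4 within the slide that holds both gave 0 genes, with 1468 at an unadjusted p under 0.05. Of the called slopes 72.4% had the same sign without day 2, against 58% over all genes for the same overlapping arrays. Without day 5, slopes past the threshold numbered 79 up and 313 down.

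By list, 38 of 44 cell cycle genes fell with day and 0 rose, with Kif23 falling by 0.93 ± 0.18 and Top2a by 0.86 ± 0.19 per day. Sarcomere genes rose in 28 of 49 cases and fell in 4, with Myl2 rising by 1.5 ± 0.38 and the titin gene Ttn falling by 0.57 ± 0.073. Satellite cell genes fell in 13 of 22 cases and rose in 2, with Fgfr4 falling by 0.90 ± 0.19 and Cd34 rising by 1.03 ± 0.19. Imprinted genes fell in 15 of 25 cases and rose in 2, with Gnas falling by 1.05 ± 0.074. Extracellular matrix genes rose in 12 of 33 cases and fell in 0, with Col1a1 rising by 1.40 ± 0.37, and fibroblast markers rose in 11 of 17, with Mfap5 rising by 1.46 ± 0.36. Oxidative phosphorylation genes rose in 13 of 37 cases, with Cox7a1 rising by 0.71 ± 0.16. Adjusted over the list alone the numbers were 40 falls for the cell cycle, 28 rises for the sarcomere, 16 falls for satellite cells, 16 falls for imprinted genes and 12 rises each for extracellular matrix, fibroblast markers and oxidative phosphorylation. Camera called the cell cycle list (adjusted p = 1.7e-12) and the imprinted (0.00029) and satellite cell (0.0039) lists down. It called the sarcomere (0.0050), extracellular matrix (0.0077) and oxidative phosphorylation (0.018) lists up. None of these calls held with an estimated correlation (adjusted p = 0.56 for imprinted genes and 0.79 for the others).

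Among the remaining lists, with no camera call for the slope, several held strong single movers. Ccn2, a TGF-beta target, rose by 1.29 ± 0.28 per day. The Wnt inhibitors Wif1 and Dkk2 rose by 1.05 ± 0.24 and 1.03 ± 0.26. Ccl9 and Ccl7 rose by 1.11 ± 0.28 and 1.0 ± 0.28, while Cxcl12 fell by 0.73 ± 0.16. Myostatin, Mstn, fell by 0.53 ± 0.088 and Cdkn1c fell by 0.84 ± 0.20. Uhrf1 fell by 0.45 ± 0.093 and Dnmt3b by 0.30 ± 0.084. Of macrophage markers Laptm5 fell by 1.01 ± 0.12 and Csf1r rose by 0.52 ± 0.11.

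The last comparison asked whether the genotype difference itself changed with day. No gene passed the limma interaction test, in which 821 genes had an unadjusted p under 0.05 against 983 expected by chance. The genes that came closest to a changing difference therefore have no call. Dnmt3a and Gdf5, set for naming in advance, kept the sign of their difference on all 4 days. Gdf7 and Myh6 did so too, but the naming rule required it, so their sign says nothing here. A constant sign is not a constant size, as Dnmt3a differed by -1.11 on day 2 and -2.39 on day 6. With 2 residual degrees of freedom the test could miss such changes.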

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

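The tests of sex-linked genes and of non-muscle markers and the comparison of slide places were chosen after the values were seen, whereas the tests of dim spots and of the course of differentiation and the counts over other splits of the arrays were written before.

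Sex-linked transcripts stood out between day 2 and the later days. The Y-linked genes were outside the fits, while Xist was in them and is among the named rises of the day slope. Y-linked genes were brighter on day 2, Eif2s3y at least 343-fold, Ddx3y at least 136-fold, Uty at least 5.24-fold by one probe and 1.45-fold by the other, and Kdm5d at least 1.74-fold. Xist was brighter on the later arrays, at least 74.8-fold by one probe and at least 36.9-fold by the other. Lower sensitivity of the later scans cannot raise Xist by 36.9-fold, so the tables argue against it as the whole cause. Male cells on days 4 to 6, as labelled, are argued against by the same values. On those arrays 0 of 4 Y-linked genes were well above background, and Xist was on all 6. Cells of the other sex than labelled on those days remain the candidate explanation. Sex, slide and scan session cannot be told apart for the 8921 day slopes, and the genotype comparison holds 1 array of each genotype on every day.

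The genotype difference changed with day for 6 lists by camera on the interaction at the preset correlation, a test added to the planned ones, and for none with an estimated correlation (adjusted p = 0.86 each). The difference of the cell cycle list moved up with day (adjusted p = 0.000102). Those of extracellular matrix (0.00146), tendon, cartilage and bone (0.00644), TGF-beta (0.00752), smooth muscle and pericyte markers (0.0158) and fibro-adipogenic and fibroblast markers (0.0339) moved down. The days did not move in steps, since the extracellular matrix medians were 0.19, -0.62, 0.21 and -0.63 on days 2, 4, 5 and 6.

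Days 4 and 6 shared much of their genotype difference, at a Pearson r across genes of 0.50. Noise of dim spots is argued against as the cause, because r was 0.65 in the 4916 brightest genes, where the other pairs of days gave 0.18 to 0.38. Whether Dnmt3a-KO cells were further along in differentiation stays open, because the day 4 difference correlated at 0.049 with the change from day 4 to day 6, but limma called 0 slopes over those days (1574 at an unadjusted p under 0.05). A lower share of non-muscle cells in Dnmt3a-KO would lower their markers, and 12 of 12 medians of the 6 non-muscle lists were below 0 on these days. On day 5 that held for 5 of 6 as well. Some medians were near 0, such as -0.029 for endothelial markers on day 6, and some lists share members. The muscle lists did not all move the other way. On days 4 and 6 the sarcomere medians were -0.19 and 0.066. Those of myogenic regulators were 0.13 and 0.088, and those of satellite cells -0.26 and -0.34. The lists therefore do not settle such a share. A lower share of non-muscle cells does not account for the cell cycle list on day 2, where that list had a median of -0.90 and the fibroblast markers 0.66. The places on the slide cannot be told apart from the day, since WT took place 1 and Dnmt3a-KO place 2 on days 4 and 6 and 0 other days had those places.

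Splits of the 8 arrays, with mirror images under the day block counted once, make 20 fits with the real one included, which are too few for a share under 0.05. Counting the real one, 2 gave at least the 2 genes past the threshold (highest other 2), 2 gave at least the 2530 genes at an unadjusted p under 0.05 (highest other 2897), and 3 gave at least the 9 list calls (highest other 11). The other split with 2897 genes keeps the genotype labels of days 4 and 6, so it carries the difference those days share. Among the 8 splits that part all 4 pairs, the real one had 2530 genes and the highest other 1429, while 2 with the real one had at least the 9 list calls (highest other 9).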

How the results depend on the processing

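Signal over background limits the genes compared, as 61.6% to 67.4% of spots were well above background. No named gene, and no list called by camera, changed its direction under an alternative in which it was past the threshold. Of 1895 alternatives over 107 values of named genes, 1827 kept their direction and side of the threshold and 28 passed it. Another 21 lost it and 19 changed direction without passing. Only Myh6 and Gm3866 of these were past it in the main fit, so all 21 losses were theirs. Most values that kept their side were thus not past it in either fit. Of 200 over 25 lists, 148 kept theirs, 9 passed, 28 lost it and 15 changed direction without a call. Those 28 losses were all among the 9 lists called in the main fit. The cause was not tested unless named. Against the 2 genes of the genotype effect, quantile scaling, median scaling, probes well above background on at least 1 array, no filter, the deposited score and no day block each gave 0. Normexp gave 35, probes above background on all 8 arrays 38, every probe 8, the trend and robust variance model 93, array weights 13, slide as the block 19, day as a random block 128 and leave-one-out 0 to 0. Gdf5 passed the threshold at 1.73 with normexp and 2.43 with array weights. Its other probe passed at 2.42 in the fit that kept every probe. Gdf5 also passed at 2.41 with probes above background on all 8 arrays and with the trend and robust model. Slide as the block and day as a random block likewise gave 2.41, past the threshold. Dnmt3a passed at -2.01 with the trend and robust model and with day as a random block. The day slope count of 8921 became 0 to 9862 leaving out 1 day, 0 for day 5 minus day 4 and 0 with slide as a fixed block, and its higher share of 57.1% became 46.6% with normexp and 20.2% in the leave-one-out run without day 5. The interaction count stayed at 0 under the scalings, background correction, filters, probe choice, deposited score, variance model, array weights and leave-one-out runs tried for it. Genes 2-fold apart on days 2, 4, 5 and 6 (1018, 1260, 950 and 1053) numbered 64, 131, 68 and 80 with normexp and 566, 674, 372 and 436 with both arrays well above background. At 1.5-fold they numbered 2708, 3076, 2390 and 2644, at 4-fold 217, 275, 232 and 272, and on day 2 with the deposited score 1756. A looser or stricter fold makes these counts larger or smaller by construction. The higher share on day 5, 35.2%, became 48.2% with quantile scaling and 45.6% with normexp, and on day 4, 38.3%, became 25.2% with normexp. The 25 genes 2-fold apart on all 4 days, 44% of them higher, became 23 with quantile scaling (56.5% higher), 3 with normexp (33.3% higher), 114 at 1.5-fold and 1 at 4-fold. Asking for 3 days, leave-one-out runs chosen after seeing the data gave 36 to 78. The 33 cell cycle genes that fell adjusted over the list alone became 1 to 38 in leave-one-out runs chosen after seeing the data. The 9 list calls, 3 up and 6 down, became 0 with an estimated correlation and 2 with fry. Leaving out day 2, 4, 5 or 6 gave 10, 6, 9 and 6 calls. Of these, 2, 2, 1 and 3 were up and 8, 4, 8 and 3 down.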

Other observations

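The tests of chance order and of copy number on chromosome 16 were chosen after the values were seen; those of other probes and of nearby spots were written before.

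A stretch of neighbouring genes on chromosome 16 was lower in Dnmt3a-KO cells by about the same amount on every day. In the order of GRCm38.p6 it held 15 measured genes from Qtrt2 to Phldb2, with medians of -0.89, -0.88, -0.93 and -0.84 on days 2, 4, 5 and 6, a level of 52.6% of WT. Among them Atp6v1a, a subunit of the vacuolar proton pump, differed by -0.999 ± 0.096 (SD over 4 days), the autophagy gene Atg3 by -0.93 ± 0.079, Gtpbp8 by -1.08 ± 0.085 and Abhd10 by -0.89 ± 0.10. Boc, a co-receptor that promotes myogenic differentiation, differed by -1.16 ± 0.73, Ccdc80 by -1.32 ± 0.32 and Cd200 by -1.04 ± 0.32. None passed the limma threshold over all genes, 13 fell adjusted over the stretch alone, which was picked on these values, and 13 of 15 were lower on all 4 days. The exceptions were Gramd1c at -0.16 and Btla at 0.15. Zbtb20, 2 genes before the stretch, differed by -1.11 and Plcxd2, just after it, by -0.62.

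The lowest running median of 9 neighbouring genes was -1.04 there, against -0.62 elsewhere in the genome, and 0 of 1000 shuffles of the gene order reached it (lowest -0.76), which argues against a chance run. A strain variant under single probes is argued against for Naa50, Abhd10, Ccdc80 and Atp6v1a by their 5 other probes, all below 0 with a median of -1.03. The other genes of the stretch had no second usable probe to check. A patch of the array surface is argued against by a median of -0.006 over 186 genes with spots nearby. Loss of 1 of 2 copies of the stretch in the Dnmt3a-KO mice is a candidate explanation, as it predicts a halving on each day, and the day farthest from it had a median of -0.84. This is a hypothesis found and tested on the same arrays, which hold no measure of DNA copy number, and an effect of Dnmt3a loss on the region stays open and untested. Named genes of the stretch, such as Usf3, Ccdc80 and Gtpbp8 among those 2-fold lower on all 4 days, carry this limit.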
